A study of Mus musculus with 8 samples.

How the data were processed

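Gene expression was measured by QuantSeq sequencing, which reads the 3′ ends of polyadenylated transcripts, in leukemic progenitor cells that the labels call I1DN. The cells grew in mice transplanted with I1DN leukemic cells. The mice received vehicle, AG120 (AG-120, ivosidenib, an inhibitor of mutant IDH1), AZA (azacitidine, a cytidine analogue that inhibits DNA methyltransferases) or both drugs for 5 days. Cells positive for cKit and negative for CD11b were isolated per mouse by flow sorting, per the labels' protocols. There were 8 libraries, 2 in each of 4 groups. Bisulfite sequencing, which the series design also mentions, was not analysed here.

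Per the submitters' processing notes, the tools were bcl2fastq 2.17.1.14, cutadapt 1.14, HISAT2 2.1.0, featureCounts, Subread 1.6.3, R 3.6.2, limma 3.42.2 and edgeR 3.28.1, and the genome build was mm10. The deposited table holds log2 CPM (log2 of counts scaled to one common library total) for 12294 genes in 8 libraries. The values show that the authors had normalized the libraries to one distribution before depositing them: every library has a maximum of 13.37, and 2 to the power of each value sums to between 999530 and 999560 per library. Library totals are lost by such scaling, so the depth of each library is unknown. Values that tie within a library keep the order of whole reads, and a gene on the k-th distinct value has at least k minus 1 reads more than the lowest class. By that count the median gene rested on at least 105 steps in the AG120_AZA replicate 2 library and on at least 149 in the AG120_AZA replicate 1 library, with the other 6 libraries between these. From 100 to 376 genes per library sat at the lowest value. From 6.85% to 11.9% of genes per library lay fewer than 10 steps above the lowest value.

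Symbols were matched to GENCODE M21, whose assembly GRCm38 is the mm10 build; 12064 of the 12294 symbols (98.1%) matched. Coordinates are those gene spans, counted from 1. The annotation the authors counted against is not given in the sources used here. In 20 sets holding 60 symbols the values were identical in all 8 libraries, the largest being 17 Pcdhg symbols, so those symbols share one measurement; 7 of the 9 Ugt1a symbols form such a set. Counting by strand is not stated in the sources used here, so overlapping and antisense genes cannot be separated.

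The log2 CPM values were used as deposited by the authors, with no further scaling and no filter. Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with a mean-variance trend. A model of 4 group means over all 8 libraries (4 residual degrees of freedom, 7.06 prior degrees of freedom) gave 5 pairwise contrasts and the AG120 by AZA interaction. An additive model (5 residual and 6.85 prior degrees of freedom) gave the main effect of each drug. The p-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 12294 genes of a comparison; a gene is called changed at an adjusted p below 0.05. Errors of fold changes are moderated standard errors and errors of group levels are SD with n = 2. All p-values in the text are adjusted unless said otherwise.

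For each of 29 gene lists fixed in advance, limma's camera compared the members' change with that of all other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 29 lists. Camera was repeated with the correlation estimated from the data, and limma's fry was run too. The fry p tests whether a list's genes move, on balance, one way, and its mixed p whether they change in either direction; neither compares the list with other genes. Members were also adjusted over the list alone. The lists were drug targets and DNA methylation enzymes, pyrimidine salvage, de novo pyrimidine synthesis, DNA replication, mitosis, p53 targets, interferon-stimulated genes, MHC antigen presentation, germline genes, imprinted genes, hematopoietic stem cell, primary granule, neutrophil maturation, monocyte, dendritic, erythroid, megakaryocyte, mast cell with basophil and eosinophil, B cell, T and NK cell, and stromal genes, hypoxia targets, cholesterol synthesis, ATF4 targets, MYC targets with ribosome biogenesis, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear-encoded oxidative phosphorylation, and immediate early with heat shock genes.

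The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, per comparison, the 10 highest and 10 lowest log2 fold changes (5 each for interaction and main effects) among called genes with mean log2 CPM of at least 3 and no overlap between the groups, skipping unnamed gene models. Where fewer than 5 genes passed in a direction, it takes the 5 with the smallest unadjusted p among genes with mean log2 CPM of at least 3, again skipping unnamed gene models. These are said not to pass. It adds up to 4 members of each list discussed, by smallest p, and all drug targets and DNA methylation enzymes. Some genes that this rule takes are not reported here.

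The procedure was tested on simulated data made from the 12294 genes' own means and a spread smoothed on the mean, with 200 genes changed per draw in 5 draws. For AG120 against vehicle it recovered 1.20% of 2-fold and 33.8% of 4-fold changes, with 5.91% false among its calls. For AG120_AZA against AZA it recovered 2.80% and 38.4%, with 4.63% false. For the AG120 main effect it recovered 22.2% and 63.4%, with 4.46% false. Genes were drawn independently of each other and with the same spread in every library. These shares therefore do not cover genes that move together or a library that lies apart.

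Alternatives were a fit without the trend, vooma precision weights, library weights, filters at mean log2 CPM of at least 3 and 5, repeated quantile normalization, median centring, only the groups compared, a block for the replicate number, and each library left out in turn. Counting identical values once was added after seeing the data. A pseudocount did not apply because the values are logarithms, and voom on recovered reads was replaced by vooma because whole reads could not be recovered for all genes.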

Results

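Expression was compared in I1DN leukemic progenitor cells from mice given vehicle, AG120, AZA or both drugs (AG120_AZA) for 5 days, with 2 libraries per group. The series design asks what combined AG-120 and azacitidine treatment does to gene expression. The labels say that cells were sorted per mouse but do not state that each library is a different mouse, so p-values measure the spread between these libraries. Replicates correlated across genes at Pearson r = 0.921 for vehicle, 0.936 for AG120, 0.927 for AZA and 0.929 for AG120_AZA; genes are not independent replicates. The libraries' scaling removed their totals, so their depth is unknown beyond the lower bounds of 105 to 149 steps for the median gene. The first principal component held 35.7% of the variance and placed the 4 libraries with AG120 above 0 and the 4 without it below 0. AG120_AZA replicate 2 lay farthest out, at 88.0.

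**Figure D1:**
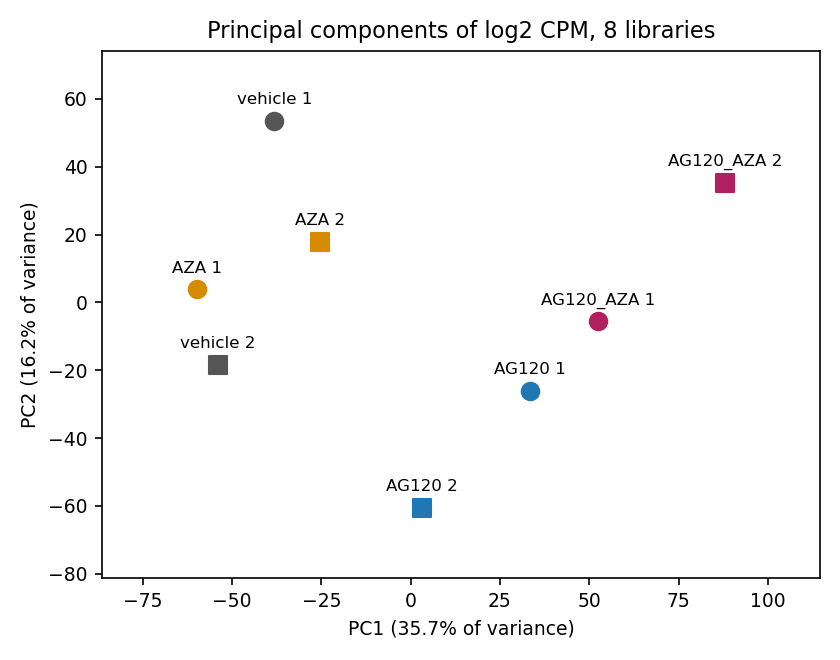
Principal components of log2 CPM over 12294 genes; the x axis is PC1 (35.7% of variance), the y axis PC2 (16.2%), each point is a library, circles are replicate 1 and squares replicate 2. The 4 libraries with AG120 lie above 0 on PC1, up to 88.0, and the 4 without it at -59.7 to -25.3.

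The targets of the drugs were measured first. Idh1 stood at 7.95 ± 0.52 log2 CPM (SD, n = 2) in vehicle, 8.44 ± 0.26 in AG120, 8.15 ± 0.10 in AZA and 7.74 ± 1.13 in AG120_AZA. Dnmt1, the maintenance DNA methyltransferase, stood at 7.96 ± 0.01, 8.01 ± 0.13, 7.68 ± 0.35 and 7.58 ± 0.06 in the same order. Of the 11 measured drug targets and DNA methylation enzymes, none was called in any of the 5 pairwise contrasts by limma. Over both AZA levels, Dnmt3a, a de novo DNA methyltransferase, fell with AG120 by 0.74 ± 0.18 (SE) on the log2 scale (adjusted p = 0.0341) and Idh2 fell by 0.56 ± 0.13 (adjusted p = 0.0317). Uhrf1, Dnmt3b, Tet1, Tet2, Tet3 and D2hgdh had log2 changes of -0.26, -0.43, -1.11, -0.35, -0.13 and -0.08 in that main effect, and none passed. The Dnmt3a call was lost without vehicle replicate 1 (adjusted p = 0.0708), AG120 replicate 1 (0.139), AZA replicate 1 (0.104), AG120_AZA replicate 1 (0.0754) and AG120_AZA replicate 2 (0.0601). The Idh2 call was lost without vehicle replicate 1 (adjusted p = 0.0520), vehicle replicate 2 (0.0595), AG120 replicate 1 (0.132), AZA replicate 1 (0.103), AG120_AZA replicate 1 (0.0832) and AG120_AZA replicate 2 (0.0693). Without the mean-variance trend neither was called (adjusted p = 0.101 and 0.119). The list as a whole was lower in AG120_AZA than in vehicle (mean log2 change -0.51, camera adjusted p = 0.0490), and that call was lost with an estimated correlation (adjusted p = 0.671 with an estimated correlation). It was also lost in 6 of 8 omissions of a library: vehicle replicate 1 (-0.42), vehicle replicate 2 (-0.60), either AG120 library (-0.51), AG120_AZA replicate 1 (-0.45) and AG120_AZA replicate 2 (-0.57).

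The effect of AG120 alone was read from AG120 against vehicle. Genes of basophils, eosinophils and the erythroid lineage were among the highest changes. Prss34, a basophil protease, went from 3.17 ± 0.56 log2 CPM (SD, n = 2) in vehicle to 7.88 ± 0.62 in AG120, a rise of 4.71 ± 0.55 (SE) on the log2 scale or 26.2-fold (adjusted p = 0.00673). Ms4a2, the beta chain of the IgE receptor, rose by 3.89 ± 0.34 (adjusted p = 0.00109). Mcpt8, another basophil protease, rose by 3.81 ± 0.33 (adjusted p = 0.00109), and Epx, eosinophil peroxidase, rose by 4.56 ± 0.78 (adjusted p = 0.0295). The early erythroid genes Rhd (4.68 ± 0.61, adjusted p = 0.00836), Car1 (3.90 ± 0.63, adjusted p = 0.0258) and Klf1, an erythroid transcription factor (3.56 ± 0.36, adjusted p = 0.00362), rose as well. Irf8, a transcription factor of monocyte and dendritic cell development, fell by 3.19 ± 0.37 (adjusted p = 0.00673).

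Also among the highest changes were Mgl2 (3.71), the metallothionein Mt2 (3.71 ± 0.41, adjusted p = 0.00552), Prg3 (3.70), an eosinophil granule protein, and Il1rl1 (3.61), the receptor of interleukin 33. Among the lowest were Thsd1 (-3.44), Gcnt2 (-3.23), Srgap3 (-2.90), Zfp467 (-2.84), Pou2f2 (-2.38), Ifi203 (-2.37), Tpm4 (-1.82) and Cd93 (-1.75), a marker of immature progenitors. Each of these genes passed the test.

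By camera, 5 gene lists were higher and 2 lower in AG120 than in vehicle. Of the 17 measured mast cell, basophil and eosinophil genes, 5 rose over all genes tested and 9 when adjusted over the list alone, and 16 had positive changes (mean log2 change 2.50, adjusted p = 2.52e-09; adjusted p = 0.241 with an estimated correlation). Of 20 erythroid genes, 4 rose and 12 had positive changes (mean 0.83, adjusted p = 0.0472; adjusted p = 0.706 with an estimated correlation), and over the list alone 9 rose and 3 fell. The globin Hbb-bs went the other way among them, with a change of -1.84 ± 0.58 that did not pass (adjusted p = 0.209). MYC targets and ribosome biogenesis genes had no member past the test over all genes and 9 of 36 adjusted over the list alone (mean 0.48, adjusted p = 9.38e-08; adjusted p = 0.706 with an estimated correlation). Rrp9 (1.19 ± 0.31), Dkc1 (0.79 ± 0.21) and Npm1 (0.61 ± 0.17) were among the leading members. Hematopoietic stem cell genes had 1 of 21 lower over all genes and, over the list alone, 7 lower and 1 higher (mean -1.06, adjusted p = 0.00168; adjusted p = 0.706 with an estimated correlation). ATF4 targets (mean 0.53, adjusted p = 0.00555) and mitochondrially encoded genes (mean 0.41, adjusted p = 0.0291) were higher and megakaryocyte genes lower (mean -0.81, adjusted p = 0.0291), with no member called among the 26, 13 and 13 measured and adjusted p = 0.706 with an estimated correlation for each. Megakaryocyte genes differed between the AG120 libraries: Pf4 stood at 9.42 and 7.15 log2 CPM there, against a vehicle mean of 10.69 ± 0.38 (SD, n = 2). When single libraries were left out, the erythroid list was called in 4 of 8 omissions, and not without AG120 replicate 1 (0.42), vehicle replicate 2 (0.90) or either AG120_AZA library (0.83). The megakaryocyte mean was -0.48 without vehicle replicate 2 and -0.17 without AG120 replicate 2, neither called, and -1.44 without AG120 replicate 1. ATF4 targets were not called without AG120 replicate 1 (0.36), nor mitochondrially encoded genes without vehicle replicate 2 (0.43) or AG120 replicate 2 (0.37). Without vehicle replicates 1 and 2, AG120 replicates 1 and 2, AZA replicates 1 and 2, and AG120_AZA replicates 1 and 2, each alone and in that order, the members called were 1, 4, 1, 3, 4, 4, 4 and 4 for erythroid genes (higher). The counts for mast cell, basophil and eosinophil genes on the higher side were 3, 7, 3, 3, 3, 3, 5 and 4. The counts for stem cell genes on the lower side were 0, 2, 0, 0, 1, 0, 1 and 1. Without AG120 replicate 1, 2 erythroid genes were called lower.

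Limma called 71 of 12294 genes in this contrast, 44 higher and 27 lower, and 1609 had an unadjusted p below 0.05. The count was 0 without the mean-variance trend, 39 with vooma, 23 of the genes with mean log2 CPM of at least 5, 18 with only the groups compared, and 8, 14, 22 and 44 without vehicle replicate 1, AG120 replicate 1, AG120 replicate 2 and AZA replicate 2. Among 23 called genes followed through these omissions, Prss34, Ms4a2, Mcpt8, Klf1, Mt2 and Irf8 passed in each of 8.

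**Figure D2:**
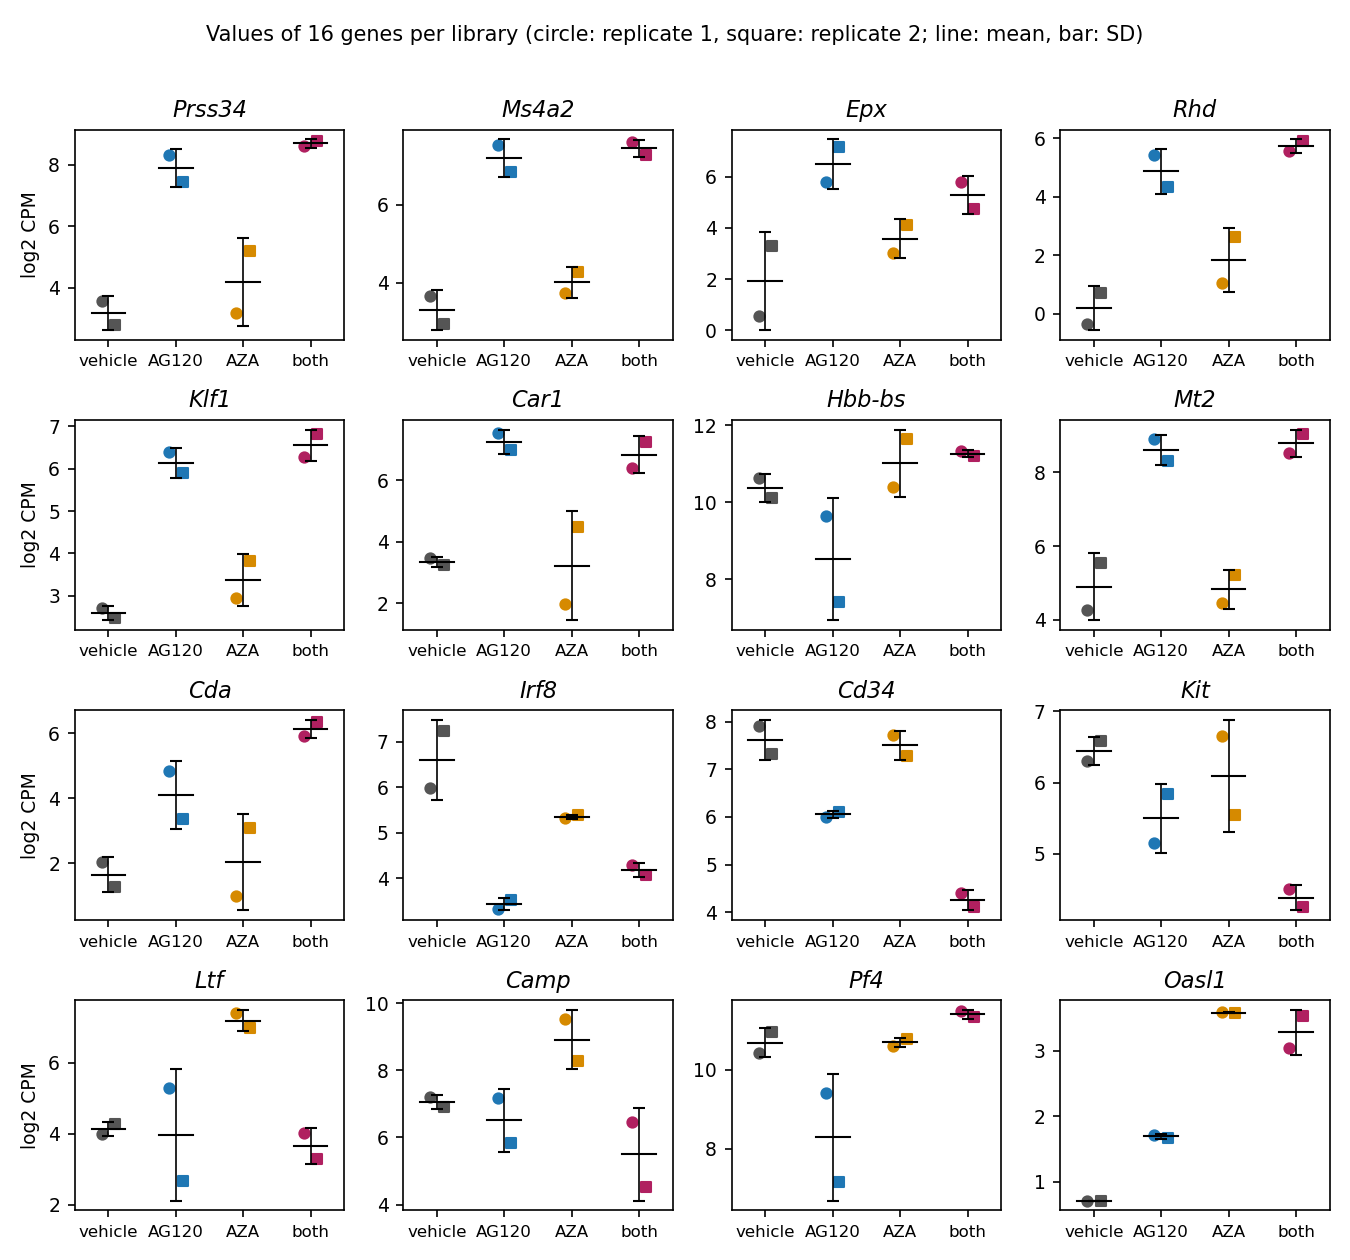
Log2 CPM (y axes) of 16 genes in the 4 treatment groups (x axes); circles are replicate 1, squares replicate 2, horizontal lines the means and bars the SD of 2 libraries. Prss34, Ms4a2, Klf1, Rhd and Mt2 lie higher in all 4 libraries with AG120 than in the 4 without it, while Hbb-bs is lowest in AG120 alone and Ltf highest in AZA alone.

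AZA against vehicle gives the effect of AZA alone. No single gene passed. Neutrophil genes were among those with the smallest unadjusted p that the naming rule took: Stfa2, a neutrophil stefin, stood at 3.13 ± 1.55 log2 CPM (SD, n = 2) in vehicle and 6.75 ± 1.05 in AZA (log2 change 3.63 ± 0.66, adjusted p = 0.461), Stfa3 differed by 3.45 ± 0.63 (adjusted p = 0.461), and Ltf, which encodes lactoferrin, by 3.05 ± 0.64 (adjusted p = 0.701). Trpm2 (2.40 ± 0.49) and Lgals3 (1.97 ± 0.41) were the other leading genes on the higher side among genes with mean log2 CPM of at least 3. On the lower side, within the same limit, Bcas3 (-1.59), Unc45a (-1.55), Pam (-1.40), Epdr1 (-1.45) and Irf8 (-1.26) had the smallest unadjusted p, and none passed. Over all genes, Xlr4c, outside that limit, had the smallest unadjusted p (limma adjusted p = 0.260).

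As groups, neutrophil maturation genes were higher in AZA: 28 of 28 measured members had positive changes, 0 passed over all genes and 7 when adjusted over the list alone (mean log2 change 1.71, camera adjusted p = 6.35e-12; adjusted p = 0.234 with an estimated correlation). Mmp9 (3.63 ± 0.87) and Retnlg (3.77 ± 0.94) were among them. Interferon-stimulated genes were higher too, with 34 of 41 positive, 0 passing over all genes and 1 over the list alone (mean 0.92, adjusted p = 6.35e-12; adjusted p = 0.222 with an estimated correlation). Oasl1 stood at 0.72 log2 CPM in both vehicle libraries and 3.58 in both AZA libraries (2.86 ± 0.50, adjusted p = 0.461). Ifit3 (5.06 ± 1.38), Oas2 (2.89 ± 0.87) and Rtp4 (1.33 ± 0.37) led the rest. The interferon signal sat in weakly expressed members: the 8 members with mean log2 CPM of at least 5 had a mean change of 0.07 ± 0.11 (SE). MHC antigen presentation genes had 17 of 19 positive (mean 0.48, adjusted p = 0.000780; adjusted p = 0.222 with an estimated correlation), led by H2-D1 (0.70 ± 0.20) and Tap1 (0.74 ± 0.24). The MHC mean was 0.23 without vehicle replicate 1, where it was not called, and 0.72 without vehicle replicate 2.

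The mast cell, basophil and eosinophil list was higher with AZA as well (mean 1.06, adjusted p = 0.000161; adjusted p = 0.234 with an estimated correlation), led by Ear2 (5.66 ± 0.96) and Mcpt8 (1.54 ± 0.33). Camera also called p53 targets (mean 0.31, adjusted p = 0.0152; adjusted p = 0.826 with an estimated correlation), immediate early and heat shock genes (0.45, adjusted p = 0.0123; adjusted p = 0.909 with an estimated correlation), cholesterol synthesis genes (0.21, adjusted p = 0.0435; adjusted p = 0.909 with an estimated correlation) and, on the lower side, the 3 measured B cell genes (-1.17, adjusted p = 0.0435; adjusted p = 0.743 with an estimated correlation). The B cell list was called in 3 of 8 omissions. It was not called without AZA replicate 1 (-0.37), vehicle replicate 1 (-1.29), vehicle replicate 2 (-1.05) or either AG120_AZA library (-1.17), and stood at -1.97 without AZA replicate 2. The p53 mean was 0.098 without vehicle replicate 2 and 0.19 without AZA replicate 2, neither called, and 0.52 without vehicle replicate 1. The immediate early list stood at -0.18 without vehicle replicate 2, at 0.30 without AZA replicate 1, where it was not called, and at 1.08 without vehicle replicate 1. The cholesterol list was called in 4 of 8 omissions. It was not called without vehicle replicate 1 (-0.063), AZA replicate 2 (0.064) or either AG120_AZA library (0.21), and stood at 0.48 without vehicle replicate 2 and 0.36 without AZA replicate 1.

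Limma called 0 of 12294 genes here, and 432 had an unadjusted p below 0.05. That is fewer than the share of 0.05 of all genes expected if none changed. The fit without the trend called 2, the fit on only these groups 1, and the fit without AG120 replicate 2 called 1.

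Both drugs together were compared with vehicle. Prss34 rose by 5.52 ± 0.55 (SE) on the log2 scale, or 46.0-fold, to 8.69 ± 0.13 log2 CPM (SD, n = 2; adjusted p = 0.00111), and Rhd by 5.52 ± 0.61 (adjusted p = 0.00198). Klf1 rose by 3.97 ± 0.36 (adjusted p = 0.000603) and Ms4a2 by 4.15 ± 0.34 (adjusted p = 0.000470). Cda, the cytidine deaminase that inactivates cytidine analogues, rose by 4.48 ± 0.68 (adjusted p = 0.00685), from 1.65 ± 0.54 log2 CPM in vehicle to 6.13 ± 0.29. Markers of immature progenitors fell: Cd34 by 3.36 ± 0.27 (adjusted p = 0.000470) and Kit, one of the sort markers, by 2.06 ± 0.37 (adjusted p = 0.0148).

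Ces2g (4.64), Atp1b2 (4.50), Samd14 (4.38), Mt2 (3.88) and Lmna (3.82), which encodes lamin A, completed the highest changes. The lowest was BC035044 (-3.73 ± 0.32, adjusted p = 0.000470), followed by Cd34 and 8 Ugt1a symbols at -3.31: Ugt1a1, Ugt1a2, Ugt1a5, Ugt1a6b, Ugt1a7c, Ugt1a8, Ugt1a9 and Ugt1a10. These belong to a cluster of glucuronosyltransferase genes that share their last exons; all but Ugt1a7c had identical values in all libraries, so those 7 are 1 measurement whose gene of origin is uncertain.

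Of 20 erythroid genes 8 rose over all genes and 11 over the list alone (mean log2 change 1.85, adjusted p = 4.40e-06; adjusted p = 0.671 with an estimated correlation). Blvrb rose by 3.76 ± 0.45 and Gata1 by 2.11 ± 0.35 among them. Mast cell, basophil and eosinophil genes had 4 of 17 higher and 11 over the list alone (mean 2.13, adjusted p = 4.40e-06; adjusted p = 0.567 with an estimated correlation). Of 25 p53 targets 5 rose, with 8 higher and 1 lower over the list alone (mean 0.92, adjusted p = 0.000148; adjusted p = 0.671 with an estimated correlation). The cyclin gene Ccng1 rose by 1.59 ± 0.27 (adjusted p = 0.0119), Phlda3 by 3.08 ± 0.59 and Psrc1 by 2.16 ± 0.44. MYC targets and ribosome biogenesis genes had 1 of 36 higher, Hspd1 (1.21 ± 0.24, adjusted p = 0.0228), and 24 over the list alone (mean 0.57, adjusted p = 1.68e-07; adjusted p = 0.671 with an estimated correlation). ATF4 targets had 0 of 26 called and 3 over the list alone (mean 0.52, adjusted p = 0.00554; adjusted p = 0.671 with an estimated correlation). Leaving out vehicle replicates 1 and 2, AG120 replicates 1 and 2, AZA replicates 1 and 2, and AG120_AZA replicates 1 and 2, one at a time in that order, gave called members of 5, 5, 7, 7, 7, 7, 5 and 3 for erythroid genes (higher). The counts for mast cell, basophil and eosinophil genes on the higher side were 5, 7, 4, 4, 3, 3, 3 and 3. The counts for p53 target genes on the higher side were 2, 1, 3, 3, 4, 4, 3 and 0. The counts for MYC target genes on the higher side were 0, 1, 1, 1, 2, 2, 3 and 0. On the lower side, 1 p53 target was called without vehicle replicate 2 and 1 without AG120_AZA replicate 1, and 1 MYC target without AG120_AZA replicate 1.

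Stem cell genes were lower as a list (mean -0.93, adjusted p = 0.0111; adjusted p = 0.671 with an estimated correlation). Cd34, Kit, Sox4 (-1.90 ± 0.40) and Erg (-1.79 ± 0.38) fell, and Gfi1b, which also acts in erythroid and megakaryocyte cells, rose by 2.20 ± 0.39. Over the list alone 9 were lower and 3 higher. Primary granule genes were lower with 0 of 19 called and 8 over the list alone (mean -1.23, adjusted p = 0.00133; adjusted p = 0.671 with an estimated correlation), and neutrophil maturation genes with 1 of 28, Lcn2, called (mean -0.94, adjusted p = 0.00331; adjusted p = 0.671 with an estimated correlation). Granule genes differed between libraries of one group: Elane stood at 7.28 and 9.53 log2 CPM in vehicle and 8.49 and 10.9 in AG120. Without vehicle replicate 2 the means of the primary granule and neutrophil lists were -0.59 and -0.63, and without AG120_AZA replicate 2 they were -0.78 and -0.45; neither list was called in either case. The primary granule mean was -1.86 without vehicle replicate 1 and the neutrophil mean -1.43 without AG120_AZA replicate 1. Without vehicle replicates 1 and 2, AG120 replicates 1 and 2, AZA replicates 1 and 2, and AG120_AZA replicates 1 and 2, each alone and in that order, the members called were 2, 3, 4, 4, 4, 4, 3 and 1 for stem cell genes (lower). The counts for neutrophil genes on the lower side were 5, 0, 1, 1, 0, 0, 2 and 0. The Gfi1b call was lost without vehicle replicate 1 and without AG120_AZA replicate 2. The Kit call was lost without vehicle replicate 2 and without AG120_AZA replicate 2.

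Limma called 371 genes, 201 higher and 170 lower, with 2631 at an unadjusted p below 0.05. The count was 43 without the trend, 82 at mean log2 CPM of at least 5 and 200 with only the groups compared. It was 234, 242, 727 and 37 without vehicle replicate 1, vehicle replicate 2, AG120_AZA replicate 1 and AG120_AZA replicate 2. Among 39 called genes followed through these omissions, 10 passed in each of 8: Prss34, Rhd, Klf1, Ms4a2, Mcpt8, Mt2, Lmna, Blvrb, BC035044 and Cd34.

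**Figure D3:**
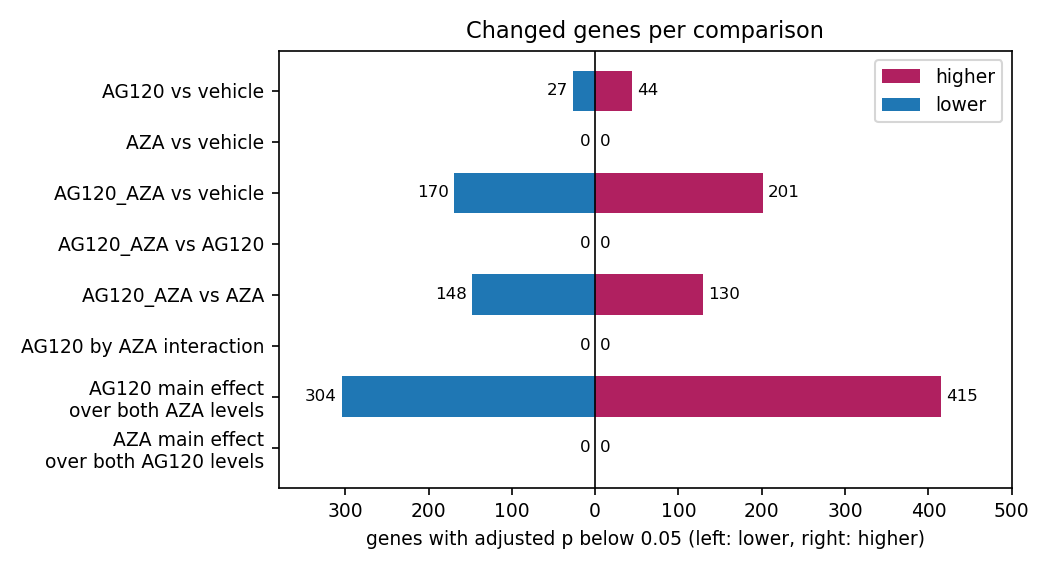
Number of genes with adjusted p below 0.05 (x axis) in each of 8 comparisons (y axis), higher to the right and lower to the left of 0. The AG120 main effect has 415 higher and 304 lower, and the comparisons AZA vs vehicle, AG120_AZA vs AG120, the interaction and the AZA main effect have 0.

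The addition of AZA to AG120 was read from AG120_AZA against AG120. No gene passed. The leading genes named here are among those with mean log2 CPM of at least 3. Pf4, platelet factor 4, stood at 8.28 ± 1.61 log2 CPM (SD, n = 2) in AG120 and 11.4 ± 0.11 in AG120_AZA (log2 change 3.12 ± 0.53, adjusted p = 0.384). Treml1, a platelet receptor (2.92 ± 0.55), Tgm2 (1.80 ± 0.32), F2rl2 (2.27 ± 0.46) and Capn3 were the other leading genes on the higher side, each at adjusted p = 0.384. On the lower side BC035044 (5.30 log2 CPM in AG120 and 3.12 in AG120_AZA, adjusted p = 0.183), Cd34 (-1.80 ± 0.27, adjusted p = 0.183), Edem2 (-1.50), Unc93b1 (-1.92) and Galns (-2.51) led, and none passed.

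Megakaryocyte genes were higher as a list, with 12 of 13 positive, 0 called over all genes and 6 over the list alone (mean log2 change 1.80, camera adjusted p = 4.20e-07; adjusted p = 0.694 with an estimated correlation). Erythroid genes had 18 of 20 positive (mean 1.02, adjusted p = 0.000168; adjusted p = 0.694 with an estimated correlation), led by the globins Hbb-bs (2.75 ± 0.58) and Hba-a1 (2.11 ± 0.58), with 5 over the list alone. Of p53 targets 22 of 25 were positive (mean 0.69, adjusted p = 0.000168; adjusted p = 0.694 with an estimated correlation), Psrc1 (1.85 ± 0.44) and Cdkn1a (1.65 ± 0.51) among them. Interferon-stimulated genes had 28 of 41 positive (mean 0.55, adjusted p = 0.00583; adjusted p = 0.694 with an estimated correlation), and over the members with mean log2 CPM of at least 5 the mean was -0.078. Primary granule genes were lower, 0 of 19 positive and 14 lower over the list alone (mean -1.40, adjusted p = 3.19e-08; adjusted p = 0.694 with an estimated correlation), with Mpo, myeloperoxidase, at -1.63 ± 0.39. Neutrophil maturation genes had 4 of 28 positive (mean -0.82, adjusted p = 0.000413; adjusted p = 0.694 with an estimated correlation). Neutrophil genes were not called without AG120 replicate 1 (-0.53) or AG120_AZA replicate 2 (-0.32), and stood at -1.31 without AG120_AZA replicate 1. Interferon genes were not called without AG120 replicate 1 (0.47) or AG120_AZA replicate 2 (0.39). Without AG120 replicate 2 the means were 1.17 for megakaryocyte, 0.61 for erythroid, 0.45 for p53 and -0.80 for primary granule genes, all called.

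Limma called 0 genes in this contrast, with 1237 at an unadjusted p below 0.05. Without AG120_AZA replicate 1 it called 213, and without AG120 replicate 1 it called 7.

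The addition of AG120 to AZA was read from AG120_AZA against AZA, which shares no library with AG120 against vehicle. Prss34 rose by 4.51 ± 0.55 (SE) on the log2 scale (adjusted p = 0.00376), Ms4a2 by 3.44 ± 0.34 (adjusted p = 0.00154), Rhd by 3.87 ± 0.61 and Mt2 by 3.96 ± 0.41 (adjusted p = 0.00196). Kcng2 (5.02), a potassium channel subunit, Atp1b2 (4.25), Cda (4.10 ± 0.68, adjusted p = 0.0131), Epdr1 (3.94), Samd14 (3.88) and Car1 (3.61) completed the highest changes. The neutrophil genes Stfa3 (-4.22 ± 0.63, adjusted p = 0.00949) and Stfa2 (-4.07 ± 0.66, adjusted p = 0.0128) fell most, and the same 8 Ugt1a symbols, Ugt1a1, Ugt1a2, Ugt1a5, Ugt1a6b, Ugt1a7c, Ugt1a8, Ugt1a9 and Ugt1a10, stood at -3.62.

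Neutrophil maturation genes fell as a group, with 8 of 28 lower over all genes and 21 over the list alone (mean log2 change -2.64, adjusted p = 1.06e-12; adjusted p = 0.369 with an estimated correlation). Ngp (-3.20 ± 0.50), Camp (-3.42 ± 0.60), Ltf (-3.53 ± 0.64) and Lcn2 (-3.03 ± 0.50) were among the 8. Of 23 monocyte genes 4 fell, Ms4a6b (-2.61 ± 0.38), Ms4a6c (-2.05 ± 0.31), Cd68 (-1.71 ± 0.30) and the lysozyme gene Lyz2 (-2.30 ± 0.51), with 9 lower and 1 higher over the list alone (mean -0.71, adjusted p = 0.0368; adjusted p = 0.576 with an estimated correlation). Of 19 MHC antigen presentation genes 4 fell, B2m (-1.09 ± 0.21), H2-D1 (-0.97 ± 0.20), Psmb8 (-1.03 ± 0.22) and Psmb9 (-2.02 ± 0.46), and 5 over the list alone (mean -0.69, adjusted p = 0.00286; adjusted p = 0.369 with an estimated correlation). Primary granule genes (mean -1.48, adjusted p = 2.49e-05; 12 lower over the list alone) and interferon-stimulated genes (mean -0.73, adjusted p = 5.29e-05; 0 over the list alone) were lower with no member called over all genes and adjusted p = 0.576 with an estimated correlation for each. The 4 MHC gene calls, in the order above, were kept in 5, 3, 3 and 1 of 8 omissions. Each was lost without AZA replicate 1 (adjusted p = 0.179, 0.191, 0.115 and 0.297), AZA replicate 2 (adjusted p = 0.0786, 0.0988, 0.141 and 0.117) and AG120_AZA replicate 2 (adjusted p = 0.197, 0.260, 0.281 and 0.197, with Psmb9 at -1.09). H2-D1, Psmb8 and Psmb9 were also lost without either AG120 library, at adjusted p from 0.0554 to 0.0654, and Psmb9 without either vehicle library (adjusted p = 0.0571 and 0.0542). The monocyte list was called in 3 of 8 omissions, and not without either AG120 library (-0.71), AZA replicate 2 (-0.72), AG120_AZA replicate 1 (-0.79) or AG120_AZA replicate 2 (-0.63). Leaving out vehicle replicates 1 and 2, AG120 replicates 1 and 2, AZA replicates 1 and 2, and AG120_AZA replicates 1 and 2, one at a time in that order, gave called members of 12, 12, 11, 11, 0, 3, 11 and 0 for neutrophil genes (lower). The counts for monocyte genes on the lower side were 7, 7, 4, 4, 0, 3, 3 and 0. The counts for MHC genes on the lower side were 3, 3, 1, 1, 0, 1, 5 and 0.

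On the higher side, 6 of 20 erythroid genes rose and 10 over the list alone (mean 1.48, adjusted p = 5.29e-05; adjusted p = 0.576 with an estimated correlation). Klf1 rose by 3.17 ± 0.36. Of 17 mast cell, basophil and eosinophil genes 3 rose and 4 over the list alone (mean 1.07, adjusted p = 0.0227; adjusted p = 0.576 with an estimated correlation). MYC targets had 0 of 36 called and 23 over the list alone (mean 0.59, adjusted p = 1.44e-08; adjusted p = 0.576 with an estimated correlation). Of 25 p53 targets 2 rose, Aen (1.25 ± 0.26) and Phlda3 (2.57 ± 0.59), and 6 over the list alone (mean 0.61, adjusted p = 0.0193; adjusted p = 0.576 with an estimated correlation). Without AG120_AZA replicate 1, p53 targets (0.57) and mast cell, basophil and eosinophil genes (0.75) were not called. Without vehicle replicates 1 and 2, AG120 replicates 1 and 2, AZA replicates 1 and 2, and AG120_AZA replicates 1 and 2, each alone and in that order, the members called were 7, 7, 6, 6, 1, 5, 5 and 1 for erythroid genes (higher). The counts for mast cell, basophil and eosinophil genes on the higher side were 4, 4, 3, 3, 2, 3, 3 and 3. The counts for p53 target genes on the higher side were 2, 2, 0, 0, 0, 1, 2 and 0. Without AG120_AZA replicate 1, 1 p53 target was called lower.

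Limma called 278 genes, 130 higher and 148 lower, with 2404 at an unadjusted p below 0.05. The count was 9 without the trend, 174 with library weights and 67 at mean log2 CPM of at least 5. It was 14, 157, 594 and 30 without AZA replicate 1, AZA replicate 2, AG120_AZA replicate 1 and AG120_AZA replicate 2. Among 42 called genes followed through these omissions, Prss34, Ms4a2, Klf1, Mt2 and Epdr1 passed in each of 8. Stfa2, Stfa3, Ngp, Camp, Ms4a6b, Ms4a6c and Cd68 passed in 6, Ltf and Lcn2 in 5, Lyz2 in 4, and Aen and Phlda3 in 3.

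**Figure D4:**
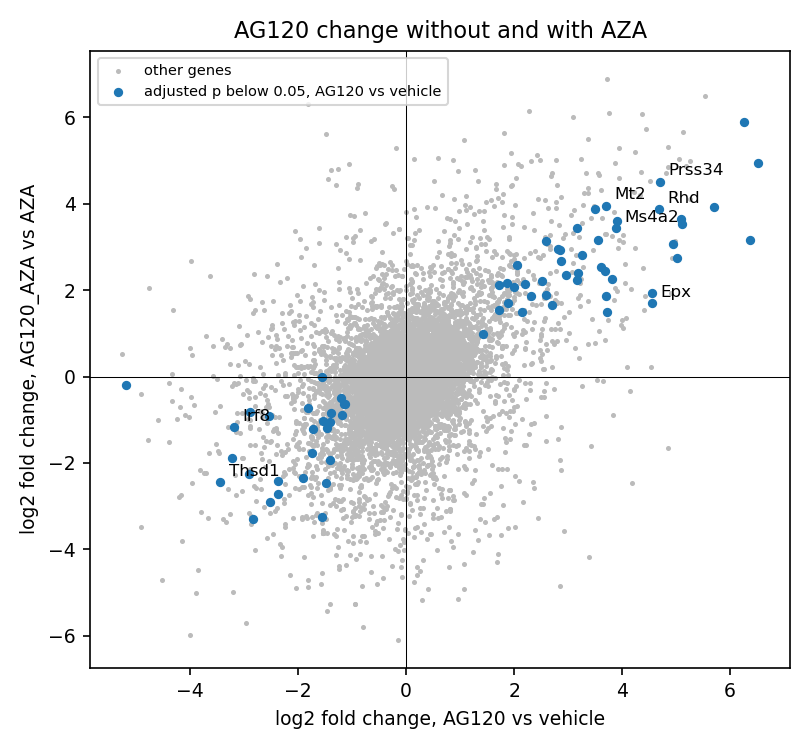
Log2 fold change of each of 12294 genes for AG120 vs vehicle (x axis) and AG120_AZA vs AZA (y axis), which share no library; blue points are the 71 genes called in AG120 vs vehicle. All 71 have the same sign in both contrasts, and the correlation across genes is 0.427.

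The changes with AG120 without and with AZA could be set side by side because those contrasts share no library. Their log2 fold changes correlated across genes at Pearson r = 0.427 (Spearman rho = 0.387), and at 0.541 over the 4760 genes with mean log2 CPM of at least 5; genes are not independent replicates. Of the 71 genes called without AZA, 71 had the same sign with AZA. Both contrasts called 33 genes higher and 13 lower, and 0 genes were called in opposite directions. Independent lists would share 0.465 and 0.325. These lists are not independent, because both contrasts use the same estimate of each gene's spread, so the excess over those values has no measured size. The changes with AZA without and with AG120, which also share no library, correlated at r = 0.0339.

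Over both AZA levels the main effect of AG120 was led by Prss34 (4.61 ± 0.37 (SE) on the log2 scale, adjusted p = 0.000100), Rhd (4.28 ± 0.43), Kcng2 (3.90 ± 0.63), Mt2 (3.83 ± 0.28, adjusted p = 7.43e-05) and Atp1b2 (3.81 ± 0.47). Zfp467 (-3.07 ± 0.36), Thsd1 (-2.94 ± 0.36), the chemokine gene Ccl5 (-2.58 ± 0.35) and Ugt1a1 and Ugt1a7c (each -2.58 ± 0.44) were among the genes that fell most. Cda rose by 3.27 ± 0.52 (adjusted p = 0.00497).

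Of 20 erythroid genes 9 rose (mean log2 change 1.16, adjusted p = 0.000895), of 17 mast cell, basophil and eosinophil genes 6 (mean 1.78, adjusted p = 1.20e-05), and of 36 MYC targets and ribosome biogenesis genes 18 (mean 0.54, adjusted p = 6.86e-11); adjusted over the list alone the counts were 10, 10 and 26. Nolc1 (0.87 ± 0.16), Hspd1 (0.90 ± 0.16) and Odc1 (0.99 ± 0.19), ornithine decarboxylase, were among the MYC targets that rose. Of 21 stem cell genes 8 fell and 1 rose (mean -0.85, adjusted p = 0.00428), Meis1 by 1.07 ± 0.25, Erg by 1.55 ± 0.26 and Cd34 by 2.40 ± 0.30 on the lower side; over the list alone 9 fell and 1 rose. Of 23 monocyte genes 8 fell (mean -0.57, adjusted p = 0.0307), among them Csf1r, the receptor of macrophage colony-stimulating factor, by 1.55 ± 0.30, with 9 lower and 1 higher over the list alone. With an estimated correlation the adjusted p was 0.473 for each of these 5 lists. The monocyte list was called in 4 of 8 omissions, and not without vehicle replicate 2 (-0.40), AG120 replicate 2 (-0.51), AZA replicate 2 (-0.55) or AG120_AZA replicate 2 (-0.51). Leaving out vehicle replicates 1 and 2, AG120 replicates 1 and 2, AZA replicates 1 and 2, and AG120_AZA replicates 1 and 2, one at a time in that order, gave called members of 10, 15, 1, 15, 7, 12, 8 and 10 for MYC target genes (higher). The counts for erythroid genes on the higher side were 9, 10, 7, 10, 9, 9, 9 and 9. The counts for mast cell, basophil and eosinophil genes on the higher side were 7, 6, 4, 7, 5, 5, 4 and 6. The counts for stem cell genes on the lower side were 5, 5, 2, 5, 5, 7, 5 and 5. The counts for monocyte genes on the lower side were 10, 6, 5, 8, 6, 6, 6 and 7. Without AG120 replicate 1, Hspd1 was the MYC target called. Without AG120 replicate 2, 2 stem cell genes were called higher.

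Fewer members were called in the other 7 lists. There were 3 higher of 26 ATF4 targets (adjusted p = 0.00296), with 6 over the list alone, 3 higher and 1 lower of 25 p53 targets (adjusted p = 0.0303), with 6 and 1 over the list alone, 1 of 13 mitochondrially encoded (adjusted p = 0.0307), with 3 over the list alone, and 2 of 50 oxidative phosphorylation genes (adjusted p = 0.0307), with 0 over the list alone, on the higher side. On the lower side were 2 of 28 neutrophil maturation genes (adjusted p = 1.20e-05), with 10 over the list alone, 1 of 41 interferon-stimulated genes (adjusted p = 0.000436), with 0 over the list alone, and 0 of 19 MHC genes (adjusted p = 0.0307), with 0 over the list alone. With an estimated correlation their adjusted p was 0.511 for p53 targets and 0.473 for the other 6. The MHC list was called in 2 of 8 omissions, without vehicle replicate 1 and AG120 replicate 1. Its mean was -0.34 without vehicle replicate 2, -0.36 without AG120 replicate 2 or AG120_AZA replicate 1, -0.25 without AZA replicate 1, -0.37 without AZA replicate 2 and -0.26 without AG120_AZA replicate 2. The oxidative phosphorylation list was called in 3 of 8, and not without vehicle replicate 1 (0.058), AG120 replicate 1 (0.090), AG120 replicate 2 (0.091), AZA replicate 2 (0.10) or AG120_AZA replicate 2 (0.12). The p53 list was not called without vehicle replicate 2, AG120 replicate 1 or AG120_AZA replicate 1 (0.37 in each). The mitochondrially encoded list was not called without vehicle replicate 2 (0.33), AG120 replicate 2 (0.31) or AZA replicate 2 (0.27). Without vehicle replicates 1 and 2, AG120 replicates 1 and 2, AZA replicates 1 and 2, and AG120_AZA replicates 1 and 2, each alone and in that order, the members called were 3, 2, 0, 2, 0, 3, 0 and 1 for ATF4 target genes (higher). The counts for p53 target genes on the higher side were 3, 1, 0, 6, 1, 1, 1 and 1. The counts for p53 target genes on the lower side were 1, 1, 0, 1, 0, 1, 1 and 0. The counts for mitochondrially encoded genes on the higher side were 0, 1, 0, 0, 0, 0, 0 and 0. The counts for oxidative phosphorylation genes on the higher side were 0, 1, 0, 0, 0, 3, 1 and 0. The counts for neutrophil genes on the lower side were 10, 0, 7, 5, 0, 0, 0 and 0. The counts for interferon-stimulated genes on the lower side were 0, 1, 0, 0, 0, 0, 0 and 1.

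Limma called 719 genes, 415 higher and 304 lower, with 2811 at an unadjusted p below 0.05. The count was 211 without the trend, 1341 with library weights and 369 at mean log2 CPM of at least 5. It was 201, 325, 389 and 413 without AG120 replicate 1, AZA replicate 1, AG120_AZA replicate 1 and AG120_AZA replicate 2. Among 70 called genes followed through these omissions, 28 passed in each of 8. Fry called 3 lists: the MYC target, mast cell, and drug target lists.

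The main effect of AZA over both AG120 levels had no gene past the test. Among genes with mean log2 CPM of at least 3, as the naming rule requires, Kdm5b, a histone H3 lysine demethylase (1.01 ± 0.18 (SE), adjusted p = 0.771), Mns1 (0.72), Nefh (1.78), F11r (1.11) and Ccdc180 (1.40) led on the higher side. Wdfy4 (-0.64), Smg6 (-0.90), Irf2bp2 (-1.10), Unc93b1 (-1.25) and BC035044 (-1.26) led on the lower. Over all genes, Oasl1, outside that limit, had the smallest unadjusted p (limma adjusted p = 0.771). Interferon-stimulated genes had 36 of 41 positive and, over the list alone, 9 higher and 1 lower (mean log2 change 0.74, camera adjusted p = 7.78e-10; adjusted p = 0.487 with an estimated correlation), with Oasl1 at 2.22 ± 0.39 and Igtp at 0.90 ± 0.23. The p53 targets had 21 of 25 positive and 3 over the list alone (mean 0.50, adjusted p = 4.07e-06; adjusted p = 0.487 with an estimated correlation), with Ccng1 at 0.77 ± 0.19. Megakaryocyte genes (mean 1.17, adjusted p = 4.07e-06; adjusted p = 0.487 with an estimated correlation) and erythroid genes (mean 0.70, adjusted p = 4.85e-05; adjusted p = 0.651 with an estimated correlation) were higher, and primary granule genes lower (mean -0.58, adjusted p = 0.00264; adjusted p = 0.862 with an estimated correlation), with 0 members of these 3 lists past the test over the list alone. Limma called 0 genes, with 761 at an unadjusted p below 0.05. Primary granule genes were not called without AG120 replicate 2 (-0.17) or AG120_AZA replicate 2 (-0.23), and stood at -0.998 without vehicle replicate 1.

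**Figure D5:**
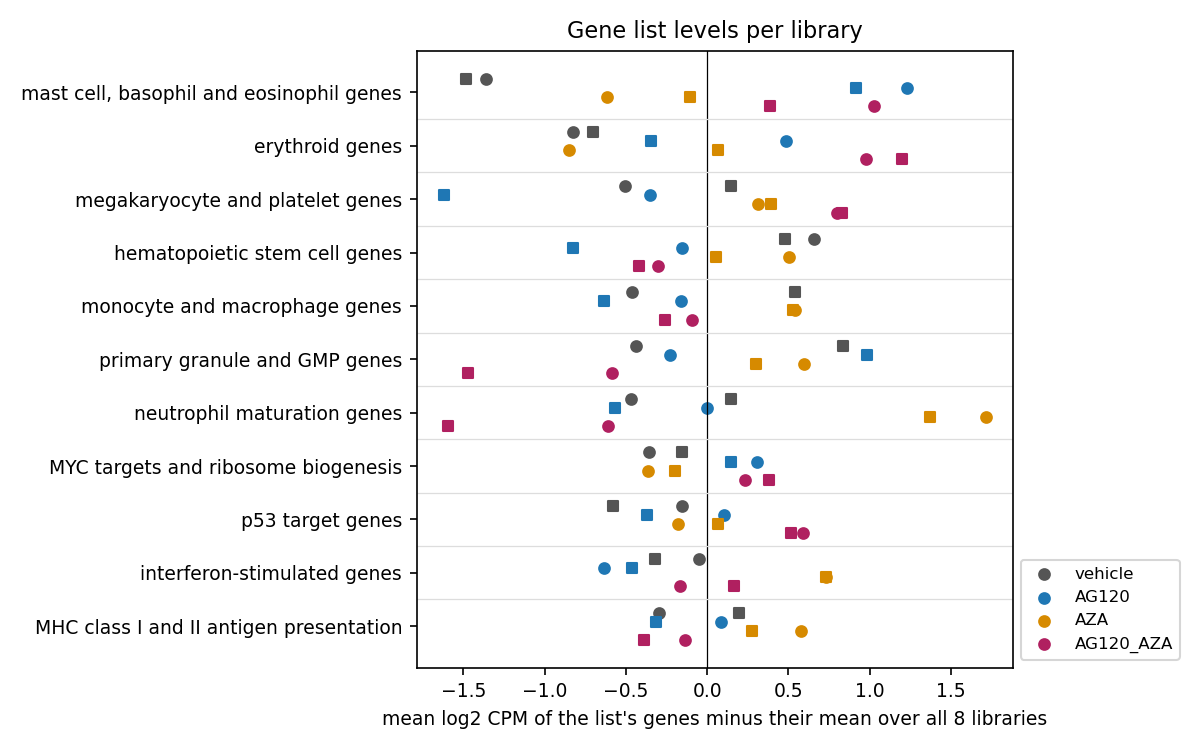
Level of 11 gene lists (y axis) in each library, as the mean log2 CPM of the list's genes minus their mean over all 8 libraries (x axis); circles are replicate 1, squares replicate 2, and colours the groups. Neutrophil maturation genes lie at 1.38 and 1.72 in AZA and at -1.59 and -0.61 in AG120_AZA, and basophil genes at -1.48 and -1.36 in vehicle and 0.91 and 1.23 in AG120.

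The interaction asks whether the change with AG120 differs when AZA is present. No gene passed. Stfa2 had the most negative value of the named genes (-5.31 ± 0.94 (SE) on the log2 scale, adjusted p = 0.794), followed by Clec4e (-2.41), Rhob (-1.78), Edem2 (-1.74) and Cd34 (-1.69). Pf4 (3.12 ± 0.75), Plxdc1 (2.46), Epdr1 (2.31), Neat1 (1.80) and Cirbp (1.55) led on the positive side among genes with mean log2 CPM of at least 3. Over all genes, Xlr4c, outside that limit, had the smallest unadjusted p (limma adjusted p = 0.196). Neutrophil maturation genes had 0 of 28 positive interactions and 13 lower over the list alone (mean -2.52, camera adjusted p = 1.47e-12; adjusted p = 0.471 with an estimated correlation). Primary granule genes (mean -1.65, adjusted p = 6.21e-08; adjusted p = 0.811 with an estimated correlation), mast cell, basophil and eosinophil genes (-1.43, adjusted p = 0.00228; adjusted p = 0.526 with an estimated correlation), MHC genes (-0.63, adjusted p = 0.0180; adjusted p = 0.471 with an estimated correlation) and interferon-stimulated genes (-0.37, adjusted p = 0.0474; adjusted p = 0.916 with an estimated correlation) were negative, and megakaryocyte genes positive (1.27, adjusted p = 0.00228; adjusted p = 0.599 with an estimated correlation). Limma called 0 genes, with 765 at an unadjusted p below 0.05; it called 29 without AG120_AZA replicate 1, 2 without vehicle replicate 2, and 1 without AG120 replicate 1 or AG120 replicate 2. The interferon list was called in 3 of 8 omissions, and not without AG120_AZA replicate 1 (-0.20), vehicle replicate 2 (-0.23), AG120 replicate 2 (-0.28) or either AZA library (-0.37). The MHC list was not called without vehicle replicate 1 (-0.38), AG120 replicate 1 (-0.43) or AZA replicate 1 (-0.48). Megakaryocyte genes were not called without vehicle replicate 2 (0.95) and stood at 0.64 without AG120 replicate 2, and primary granule genes stood at -1.02 without vehicle replicate 1 and -1.05 without AG120 replicate 2.

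There were 11 lists called in none of the 8 comparisons. In AG120_AZA against vehicle the mean log2 changes were 0.09 for DNA replication (camera adjusted p = 0.579), 0.13 for mitosis (adjusted p = 0.238), 0.32 for pyrimidine salvage (adjusted p = 0.319), 0.26 for de novo pyrimidine synthesis (adjusted p = 0.281), 0.06 for cytosolic ribosomal proteins (adjusted p = 0.702) and -0.32 for hypoxia targets (adjusted p = 0.205). The 7 imprinted genes averaged 0.85 (adjusted p = 0.784), the 3 germline genes -0.64 (adjusted p = 0.643), the 7 dendritic cell genes 0.02 (adjusted p = 0.980), the 7 T and NK cell genes 0.49 (adjusted p = 0.579) and the 4 stromal genes 0.38 (adjusted p = 0.591). Among their members, 1 DNA replication gene, 1 imprinted gene and Cda were higher over all genes tested, and 1 dendritic cell gene was higher and 1 lower. Across the 8 comparisons and 62 list calls with the preset correlation, 0 held with an estimated correlation and 4 with fry. Fry called the mast cell, basophil and eosinophil list in AG120 against vehicle (adjusted p = 0.0266), in AG120_AZA against vehicle (adjusted p = 0.0417) and in the AG120 main effect (adjusted p = 0.0322), and the MYC list in that main effect (adjusted p = 0.0320). It also called the drug target list there (adjusted p = 0.0322), which camera did not. In AG120 against vehicle the dendritic list had a mean of -0.57 and a median of 0.38.

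In the GRCm38 annotation, Prss34 lies on chromosome 17 at 25298394 to 25300165, Ms4a2 on chromosome 19 at 11615523 to 11623719, Klf1 on chromosome 8 at 84901928 to 84905291, Irf8 on chromosome 8 at 120736358 to 120756694, Cd34 on chromosome 1 at 194938819 to 194961279 and Cda on chromosome 4 at 138338424 to 138367992; all 6 are protein-coding.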

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

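The tests of erythroid cells, cell type shares, neutrophils, interferon genes and single libraries were chosen only after the results were seen, and the bars of 2 SE for neutrophils with AG120 present and for late neutrophil genes were set after those values were known; the counts over other splits of the libraries were planned.

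The change with AG120 differed between cells without and with AZA for 6 gene lists, by camera on the interaction. The mean log2 difference, AG120 change with AZA minus without, was -2.52 for neutrophil maturation genes (adjusted p = 1.47e-12), -1.65 for primary granule genes (6.21e-08), -1.43 for mast cell, basophil and eosinophil genes (0.00228), 1.27 for megakaryocyte genes (0.00228), -0.63 for MHC genes (0.0180) and -0.37 for interferon-stimulated genes (0.0474). With an estimated correlation the adjusted p ran from 0.471 to 0.916, so none of the 6 held there.

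In AG120 against vehicle, 5 of 17 mast cell, basophil and eosinophil genes and 4 of 20 erythroid genes rose, while the list calls were lost with an estimated correlation (adjusted p = 0.241 and 0.706). Without vehicle replicate 1 or AG120 replicate 1 these counts were 3 and 1, without AG120 replicate 2 they were 3 and 3, and without either AZA library 3 and 4; without vehicle replicate 2 the first was 7. Mature erythroid cells in the sort are argued against, for AG120 alone, by the 4 globin transcripts, their most abundant RNAs, of which none rose. Their median log2 change was -1.60 and the highest was -1.08. Over omissions of a library the median ran from -2.63 without AG120 replicate 1 to -0.57 without AG120 replicate 2, where the highest was -0.12. The 4 called erythroid genes had a median of 3.73 (3.46 to 3.99 over omissions). They were picked by their rise in this contrast, so the gap between them and the globins is no test. Of the 20 erythroid genes, 11 had a vehicle mean of at least 3 log2 CPM and 1 is in another list. With both drugs mature erythroid cells stay open: the globins Hbb-bs and Hba-a1 led the higher erythroid list in AG120_AZA against AG120, where no gene passed. A general fall in the share of the main cell type would raise lists of other cell types alike. The megakaryocyte, monocyte, neutrophil, B cell and T and NK cell lists changed by -0.84 to 0.17 and are not shown to differ among themselves. The mast cell, basophil and eosinophil list, which is the pattern itself, rose by 2.50 ± 0.31 (SE). That rise was not shared by these lists. Its gap of 3.34 ± 0.66 (SE) to the B cell list joins the highest and lowest lists, picked from their values. The gap therefore does not decide this explanation. A shift in the kinds of progenitors within the cKit-positive, CD11b-negative sort may also account for the rise. So may an effect of AG120 on each cell, and no test here separates these.

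Over both AZA levels, 1 of 34 splits of the 8 libraries called as many genes as the 719 of the real AG120 split, the real one itself. The highest other called 103. The share of 1 of 34 is the lowest that this count can give, so it does not exclude chance. The other splits mix libraries with and without AG120, so 103 is not a count for unchanged genes. For AZA the real count was 0, which fixes that 34 of 34 splits called at least as many, so this count says nothing about chance. The highest other split called 62, which may point to a structure of the samples; none was tested.

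Interferon-stimulated genes were higher as a list with AZA, with 0 members called over all genes and adjusted p = 0.222 without and 0.694 with AG120 present under an estimated correlation. Without AG120, neutrophils in the sort stay open as a source. Their maturation list was higher by 1.71 ± 0.47 (SE) in the same contrast, which does not show that they carry the interferon genes. The CD11b-negative gate would remove mature neutrophils, but the purity of the sorts was not measured here. The whole interferon list changed by 0.92 ± 0.16 (SE), and its 8 members with mean log2 CPM of at least 5 by 0.07 ± 0.11 (SE). The change thus sat in weakly expressed members. That filter drops weak members whether they changed or not, so it does not tell noise in them apart from an effect. With AG120 present, neutrophils stay open: their list changed by -0.82 ± 0.47 (SE), under 2 SE, and by -0.32 without AG120_AZA replicate 2 and -0.53 without AG120 replicate 1, while the interferon list changed by 0.55 (0.47 without AG120 replicate 1 and 0.39 without AG120_AZA replicate 2, neither called). The list mean of 0.55 ± 0.16 (SE) becomes -0.078 ± 0.11 (SE) over the 8 members with mean log2 CPM of at least 5. This filter again cannot tell an effect of AZA on weakly expressed members apart from noise in them.

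Neutrophil maturation genes were higher as a list with AZA alone and lower with both drugs, against vehicle, with adjusted p = 0.234 and 0.671 under an estimated correlation; the lower call was lost without vehicle replicate 2 (-0.63) and without AG120_AZA replicate 2 (-0.45). Without AG120_AZA replicate 2 the interaction mean was -2.03 ± 0.58 (SE). That mean includes the rise of 1.71 ± 0.47 (SE) in AZA against vehicle, which does not use that library. It therefore does not test whether that library alone made the genes lower with both drugs. Without it the change in AG120_AZA against AG120 was -0.32. Mature neutrophils in the AZA sorts stay open: 8 late neutrophil genes exceeded the primary granule genes by 2.66 ± 1.68 in AZA against vehicle, less than 2 SE, and S100a8, an abundant neutrophil transcript, stood at 11.5 log2 CPM in vehicle and 12.4 in AZA. The CD11b-negative gate would remove such cells, but the purity of the sorts was not measured here. Itgam, which encodes CD11b, was detected in all 4 groups and was highest in AZA. As 20 of the 28 genes had a vehicle mean of at least 3 log2 CPM, the leukemic cells may express them. The vehicle sorts could also hold neutrophils, so these levels do not decide it. No list shares these genes (0 of 28). An effect of the drugs on differentiation was not tested.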

How the results depend on the processing

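Counting symbols with identical values once was chosen only after the data were seen; the other alternatives were planned.

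Gene counts moved as follows, in the order AG120 against vehicle, AZA against vehicle, AG120_AZA against vehicle, AG120_AZA against AZA and the AG120 main effect, from 71, 0, 371, 278 and 719. Without the mean-variance trend they were 0, 2, 43, 9 and 211. With mean log2 CPM of at least 5 they were 23, 0, 82, 67 and 369, with fewer genes tested. With only the groups compared, the first 4 were 18, 1, 200 and 297. Vooma gave 39, 0, 290, 236 and 691, and library weights 98, 0, 248, 174 and 1341. The cause of these changes, apart from the filter, was not tested. The replicate numbers were not taken to pair the samples: replicate differences correlated at 0.388 between vehicle and AG120 and at 0.299 between AZA and AG120_AZA, but at -0.187 to -0.0653 between the other groups. A block for them gave 60, 0, 370, 213 and 725. That block is a term shared by all 4 groups, so it could not capture replicate shifts that go opposite ways in different groups. Symbols with identical values counted once gave 72, 0, 362, 260 and 710.

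List calls, from 7, 8, 9, 6, 9, 6, 12 and 5 in the 8 comparisons, were 0 in each with an estimated correlation, and 1, 0, 1, 0, 0, 0, 3 and 0 with fry. With the block for replicate numbers they were 6, 6, 8, 6, 8, 8, 12 and 5. Calls lost there were erythroid genes in AG120 against vehicle, B cell and cholesterol genes in AZA against vehicle, drug targets in AG120_AZA against vehicle, and monocyte genes in AG120_AZA against AZA. With mean log2 CPM of at least 5, AZA against vehicle had 4. Repeating the quantile normalization moved values by at most 0.221, and median centring moved libraries by at most 0.00448, so these say little about stability.

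Leaving out each library in turn, where the lone library of a group is assumed to vary like the other groups, gave 8 to 103 genes for AG120 against vehicle, 0 to 1 for AZA against vehicle, 37 to 727 for AG120_AZA against vehicle, 0 to 213 for AG120_AZA against AG120, 14 to 594 for AG120_AZA against AZA, 0 to 29 for the interaction, 201 to 771 for the AG120 main effect and 0 to 0 for the AZA main effect. The lowest and highest came without vehicle replicate 1 (8) and vehicle replicate 2 (103), AG120 replicate 2 (1), AG120_AZA replicate 2 (37) and replicate 1 (727, 213, 594 and 29), AZA replicate 1 (14), and AG120 replicate 1 (201) and vehicle replicate 1 (771). List calls ran from 6 to 10, 5 to 10, 7 to 11, 4 to 7, 6 to 11, 5 to 8, 8 to 12 and 5 to 11.

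Direction turned in 5 cases. In AZA against vehicle, over the omissions, cholesterol synthesis genes ran from -0.063 (without vehicle replicate 1) to 0.48, immediate early and heat shock genes from -0.18 (without vehicle replicate 2) to 1.08, Klf2 from -0.092 (without vehicle replicate 2) to 2.49, and Cd79b from -1.15 to 0.53 (without AZA replicate 1). In AG120_AZA against AG120, interferon-stimulated genes at mean log2 CPM of at least 5 had a mean of -0.078, and the cause was not tested. Of the named genes' calls, 146 of 174 were lost without the trend and 417 of 1392 over all omissions, while 51 uncalled values gained a call. Scaling by the authors removed the library totals, so what depth limits could not be measured.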

Other observations

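The test of near-silent genes was written before its result was seen, but its margin of 1 SE was set only after.

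Cda was the one pyrimidine salvage gene called: it stood at 1.65 log2 CPM in vehicle, 4.09 in AG120, 2.02 in AZA and 6.13 in AG120_AZA. Lgals3, which encodes galectin 3, stood at 3.04 ± 0.17 log2 CPM (SD, n = 2) in vehicle, 4.71 ± 0.92 in AG120, 5.01 ± 0.25 in AZA and 5.47 ± 0.35 in AG120_AZA, and rose by 2.44 ± 0.41 (SE) with both drugs (limma adjusted p = 0.0116). Itgam, which encodes CD11b, the marker absent by gate, stood at 3.22, 3.13, 3.86 and 3.06 in the same order.

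A hypothesis was that AZA raises genes near silent without it. Such genes should then exceed the others in median log2 change by more than 0.1 in both AZA contrasts and not in the AG120 contrasts. The difference was -0.02 for AZA against vehicle and 0.48 for AG120_AZA against AG120, while it was 0.24 for AG120 against vehicle and 0.85 for AG120_AZA against AZA. The value of -0.0201 ± 0.118 (SE) is below 0.1 by slightly more than its SE, so the first part of the prediction was narrowly not met. The difference of 0.85 ± 0.19 in AG120_AZA against AZA goes against its second part. Near-silent genes lie close to each library's lowest value, which differed. It was -2.74 in vehicle replicate 1, with 376 genes at it, and -3.63 in AG120_AZA replicate 1, with 100. Such differences may shift the medians of contrasts whose groups differ in lowest value, so the first part of the prediction is not decided. The AZA and AG120_AZA groups had the same lowest values, -3.63 in replicate 1 and -3.43 in replicate 2. Different lowest values therefore do not account for the 0.85, and the second part of the prediction was not met.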
